A study of Mus musculus with 4 samples.

How the data were processed

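RNA-seq libraries from WT and MSC KO induced Treg cells, 2 of each, were deposited by the authors as 2 gene-level tables, WT 1 with MSC KO 1 and WT 2 with MSC KO 2. Per the submitters' processing notes, reads were aligned to the mouse genome mm9 with TopHat, and the program version and the gene annotation are not given in the sources used here. The layout of the deposited tables is that of Cuffdiff's gene-level test output, although the notes do not name that program. The labels and tables do not name the unit, and the deposited values were read as FPKM from the layout and the values, one column per library, beside the authors' p-value and q-value for each gene. In rows with both values above 0, the deposited log2 fold change matched the ratio of the 2 values within 1.3e-05 in the first table and 1.5e-05 in the second, and rows marked significant had a q-value of up to 0.0474 and 0.0456. The fold change column of the deposited tables held #NAME? in 743 and 896 rows. Whether the authors normalized the deposited tables together is not stated, and they were treated as normalized apart.

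The tables held 24366 and 24752 rows. Rows with no gene symbol, 1925 and 2325, held 49.9% of the summed FPKM in WT 1, 54.1% in MSC KO 1, 52.2% in WT 2 and 53.2% in MSC KO 2 and were left out of the comparisons. Of several rows with 1 symbol the row with the highest mean was used. Symbols present in both tables numbered 22153, of which 3 were dropped because their rows lay at loci that did not overlap, and 6 because the authors' estimate had failed in a table (3 rows in each table). Per table, 24 symbols read as dates and could not be matched. Rows naming several genes, 206 and 219, were not split, so that Tnfrsf4, joined with Sdf4 in the first table, was not analysed. Positions are mm9 as the tables give them and were not converted.

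The tables give no read totals. Depth was estimated from the smallest step between low values of genes with a single annotated transcript longer than 2500 bp, in 27, 40, 45 and 26 genes for WT 1, WT 2, MSC KO 1 and MSC KO 2, with transcript lengths from GENCODE M21 matched by gene name only. The ratio of Msc fragments was given with exact Clopper-Pearson limits of the share of fragments, at 95%, which cover counting error only.

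Values were taken as log2(FPKM + 1), with genes of a mean of at least 1 FPKM over the 4 libraries. MSC KO was compared with WT by limma 3.58.1 in R 4.3.3 with the table as a block and a trended prior variance, two-sided, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The prior had 2.36 degrees of freedom and the residual 1. The block was in the design because the tables may have been scaled apart. Gene lists, 26 in all, were tested by camera with a preset inter-gene correlation of 0.01 where at least 3 members had been tested, and adjusted over the lists. The camera test with an estimated correlation and fry, which asks whether a list's genes move on balance one way without comparing them with other genes, stood beside it. Within each list, p-values were also adjusted over the list alone. The lists covered the Th2, Treg, Th1, Th17 and follicular helper programs, TGF-beta and interleukin-2 responses, naive and memory, activation, inhibitory receptor, cytotoxicity, chemokine receptor, interferon, cell cycle, glycolysis, oxidative phosphorylation, cholesterol synthesis, unfolded protein, ribosomal protein and E protein genes, markers of B, myeloid, mast, CD8 and gamma delta, and erythroid cells, and stress genes. Some genes, such as Gzmb, stand in more than 1 list. Genes near Msc were compared with all others by Fisher's exact test within 10 Mb and, as an alternative, 5 Mb. Tables were prepared in Python 3.11.15 with pandas 2.3.3.

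The comparison, the tests, the lists and the rule for named genes were chosen before the data were examined. The rule took Msc, Foxp3, Gata3, Il4, Il5, Il13, Il2ra, Ctla4, Ikzf2, Tbx21, Ifng, Il17a and Bcl6 among a set of fixed genes, the 10 largest rises and 10 largest falls among called genes, and up to 4 members of each list with the largest difference in the table where it was smaller, same sign in both. As 1 gene was called, the other places went to genes that did not pass, ranked by the smaller of their 2 differences. Symbols that start with Gm and a digit, Mir or Snor, or end with Rik, were not named among the largest differences, which leaves in the small RNA gene Rnu73b, and some genes that the rule takes are not reported here. Members that passed when adjusted over a list alone, and genes named among the authors' calls, are further to that rule and were chosen after their values were seen.

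On simulated data with 200 planted genes among 10603, the test recovered 1% of genes changed 2-fold and 81% of genes changed 4-fold, with 3 false among 85 calls. The simulation gave the 4 libraries of a gene the same spread. Each planted gene had the same effect in both pairs, and genes of low WT level were not planted. In the data the MSC KO-labelled pair spread 2.25 to 3.94 times as widely as the WT pair. The shares recovered need not hold there. Alternatives tried were no table block, pseudocounts of 0.1 and 0.5, no filter, a mean of at least 5 FPKM, rescaling each library to the same sum, quantile normalization, centring each table on its median, a prior without trend, summed rows, a threshold of 0.1, a 1.5-fold limit, and leaving out each pair and each library. A robust prior, failed estimates kept, the WT libraries averaged as 1 sample, and small RNA symbols left out were added after the data were seen.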

Results

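RNA was sequenced from induced regulatory T cells (induced Treg cells) of C57BL/6 mice. The cells had been cultured from sorted naive T cells for 3 days on plate-bound antibodies to CD3 and CD28 (1 µg/ml), which trigger the T cell receptor and its co-stimulatory receptor, with TGF-beta (2 ng/ml), the cytokine that induces Foxp3. There were 4 libraries, 2 labelled WT and 2 labelled MSC KO, where MSC is musculin, a basic helix-loop-helix transcription factor encoded by Msc. The deposited values were read as FPKM, fragments per kilobase of transcript scaled to the mapped fragments. The authors deposited 2 tables, WT 1 with MSC KO 1 and WT 2 with MSC KO 2. Depth was estimated from the smallest step between low values, and was 25500000 fragments in WT 1, 36500000 in WT 2, 28100000 in MSC KO 1 and 33800000 in MSC KO 2. Entries with a gene symbol at 1 FPKM or more numbered 10418 in WT 1, 10456 in WT 2, 10518 in MSC KO 1 and 10614 in MSC KO 2.

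The comparison of MSC KO with WT addressed how musculin shapes the transcripts of induced Treg cells, and in particular whether it restrains the type 2 helper (Th2) program. In both tables the libraries labelled MSC KO held less Foxp3, the transcription factor that defines Treg cells, at 2.97 and 7.05 FPKM against 62.8 and 66 FPKM in WT. Higher in both MSC KO-labelled libraries were the cytokine genes Il17f (198 and 334 FPKM against 4.4 and 3.39 FPKM), Il13 (58.1 and 21.7 FPKM against 1.43 and 2.06 FPKM) and Il4 (23.9 and 8.47 FPKM against 1.71 and 1.46 FPKM). Klf2, a transcription factor of quiescent T cells, was at 4.76 and 5.24 FPKM against 56.7 and 53 FPKM. Levels are written in the order of replicate 1 and replicate 2. The labels do not say whether the 2 tables were normalized together, so the comparison rested on the difference within a table.

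Msc itself went against the labels. On chromosome 1 (mm9, 14743428 to 14746047), it was at 0.331 FPKM in MSC KO 1 and 0.939 FPKM in MSC KO 2, and at 0.0243 FPKM in WT 1 and 0.0178 FPKM in WT 2. With the longest of its 4 annotated transcripts (1741 bp) these values correspond to about 16.2 and 55.3 fragments in the MSC KO-labelled libraries and 1.1 fragments in each WT library. As labelled, the WT cells thus held almost no Msc transcript when sequenced. The differences below cannot be read as following a loss of Msc transcripts at that time. From the rounded fragments, Msc was 14.5 times the WT value in the first table (95% interval 2.26 to 609.0, exact Clopper-Pearson limits, counting error only) and 59.4 times in the second (10.2 to 2390.0). Msc stayed under the filter of the limma fit, and with no filter on low values it did not pass (0.65 ± 0.16, adjusted p = 0.265, limma). The authors' own test of 1 library against 1 left Msc untested in the first table and did not call it in the second (q = 0.999). The labels do not say which part of the gene was targeted. Every direction below is therefore given for the libraries as labelled.

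**Figure D1:**
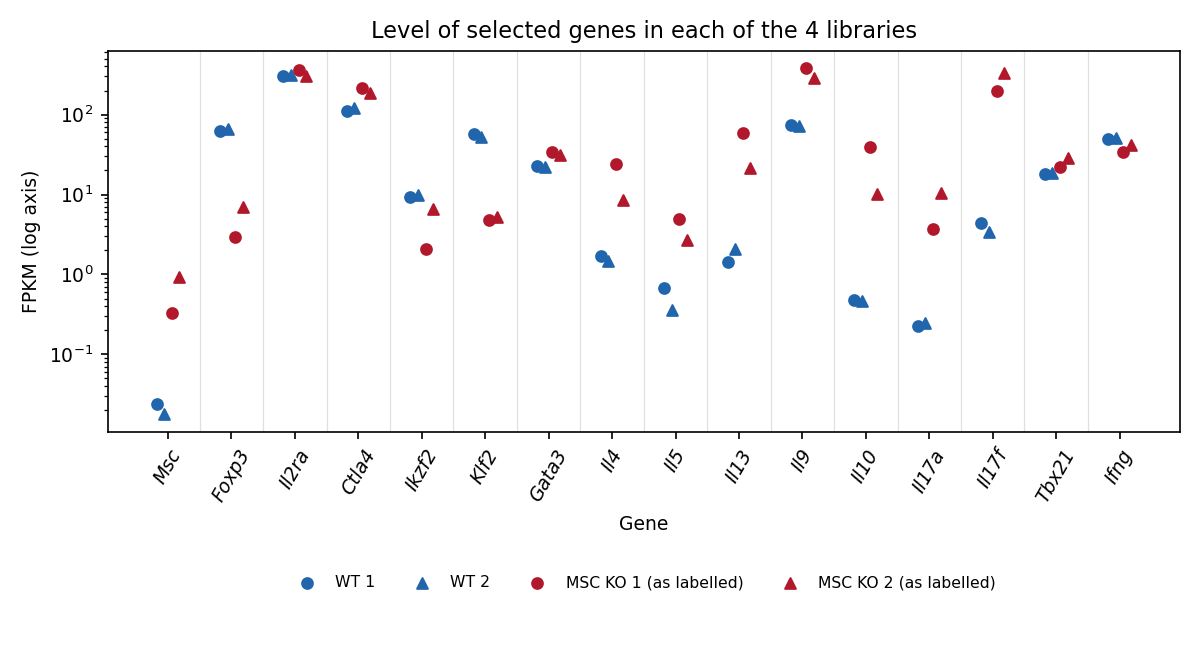
FPKM on a log axis of selected genes in WT 1 and WT 2 (blue) and in the libraries labelled MSC KO 1 and MSC KO 2 (red), 1 point per library, with circles for the first table and triangles for the second. Foxp3 and Klf2 are lower and Msc, Il13, Il17f and Il10 higher in both red points, while Il2ra lies between 302 and 364 FPKM in all 4 libraries.

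Of 10603 genes tested by limma with the table as a block, 1 passed an adjusted p of 0.05. There were 2162 with an unadjusted p under 0.05. The gene was Rnu73b, a small RNA gene (listed at a locus on chromosome 3, mm9, 85941861 to 85946590, which need not be the extent of the gene). It rose from a listed value of 0 in both WT libraries to 110 and 135 FPKM in the MSC KO-labelled ones (adjusted p = 0.0402). The authors' own test of 1 library against 1 did not call it in either table (q = 0.184 and 0.237). In the limma fit, 1 residual degree of freedom was left. Genes at least 2-fold apart on the log2(FPKM + 1) scale in the same direction in both tables numbered 226. Of these, 140 were higher and 86 lower in the MSC KO-labelled libraries, while 26 genes were 2-fold apart in opposite directions. Small RNA symbols, the class of Rnu73b, were 146 of the tested genes, and 27 of them were 2-fold apart in both tables in the same direction and 17 in opposite directions, a count made after the data were seen. Across genes, which are not independent replicates, the differences of the 2 tables had a Pearson r of 0.34 and a Spearman rho of 0.54. The agreement of the 2 tables across genes was a Pearson r of 0.58 with small RNA symbols left out. The share of genes with the same sign in both was 68.6%. All these measures of agreement would be raised if WT 1 and WT 2 came from 1 culture or RNA pool, which the labels leave open. The count of called genes depended on settings and libraries. It was 153 with no table block (78 higher, 75 lower) and 26 with small RNA symbols left out (16 higher, 10 lower; chosen after the data were seen). It was 0 without WT 1, 3 without WT 2, 2301 without MSC KO 1 and 2672 without MSC KO 2. Each fit without a library had no block, and the lone sample was taken to vary like the other group. Rnu73b no longer passed with no filter on low values (adjusted p = 0.206), quantile normalization (0.105) or a prior without trend (0.0832), nor without WT 1 (0.0951) or WT 2 (0.0507). P-values here measure only the spread between these samples, which may be technical, since the labels do not say whether replicates came from separate animals or cultures.

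**Figure D2:**
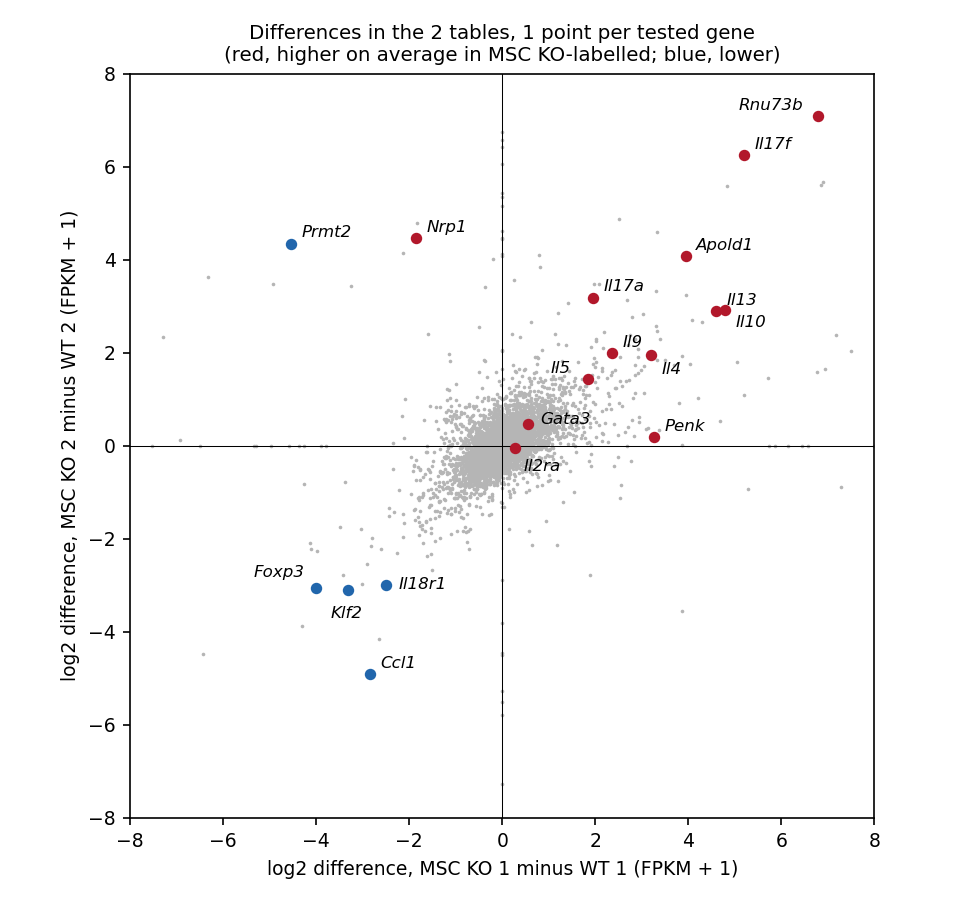
Difference of each of 10603 tested genes on the log2(FPKM + 1) scale, MSC KO 1 minus WT 1 on the horizontal axis and MSC KO 2 minus WT 2 on the vertical axis, with named genes red where their mean difference is above 0 and blue where it is below. Foxp3 (-4.01 and -3.06) and Il17f (5.2 and 6.25) lie far out in the same direction in both tables, while Prmt2 (-4.54 and 4.34) and Nrp1 (-1.85 and 4.47) lie in opposite directions.

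The largest differences shared by both tables, Rnu73b aside, did not pass the threshold over all genes. Differences are on the log2(FPKM + 1) scale with their standard error, and understate the fold of genes at low FPKM. Above WT were Il17f (5.73 ± 0.3, adjusted p = 0.0992, limma) and Apold1 (4.01 ± 0.1, adjusted p = 0.0639). So were Il10, an anti-inflammatory cytokine (3.85 ± 0.52, adjusted p = 0.139), Il13 (3.75 ± 0.48, adjusted p = 0.13) and Asb2, a substrate adaptor of a ubiquitin ligase (3.59 ± 0.22, adjusted p = 0.0992). Rps6ka4, a stress-activated kinase (413 and 120 FPKM against 20.2 and 18.2), and Timp1, an inhibitor of matrix metalloproteinases (161 and 44.2 against 8.67 and 5.94), were higher in both MSC KO-labelled libraries. The kinase gene Dclk1 (8.93 and 14.3 against 0.557 and 0.751) and Tg, thyroglobulin (23.8 and 24 against 2.59 and 2.68), were higher there too. Below WT were Ccl1, a ligand of the receptor CCR8 (-3.88 ± 0.57, adjusted p = 0.139), and Foxp3 (-3.53 ± 0.27, adjusted p = 0.114). The chemokine gene Xcl1 (-3.4 ± 0.42, adjusted p = 0.13) and Klf2 (-3.22 ± 0.1, adjusted p = 0.0706) lay below WT too. Il18r1, a subunit of the interleukin-18 receptor, was at 4.57 and 3.31 FPKM against 30.7 and 33.3. Atp1b1, a subunit of the sodium pump, was at 1.15 and 6.17 FPKM against 33.1 and 33.6, and the interferon-inducible Ifi203 at 0.204 and 1.09 against 11.9 and 13.3. Ubd, a ubiquitin-like protein, was at 0.413 and 0.326 FPKM against 9.6 and 6.69, and the tetraspanin gene Tspan9 at 0.481 and 0.618 against 6.15 and 7.05. Several of these genes passed under settings named above. With small RNA symbols left out, Il17f (adjusted p = 0.0419), Apold1 (0.0261) and Klf2 (0.0261) passed, and with no table block Foxp3 did (0.0471).

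The Th2 list, 30 genes fixed with all other lists before the data were examined, was higher in the MSC KO-labelled libraries. Of its 22 tested members 20 were higher in both tables and 1 was lower in both, with a median difference of 0.97 (1.34 in the first table, 0.38 in the second). With no filter on low values the median was 0.69 over 30 members. The list rose by camera with a preset correlation (adjusted p = 2.59e-07; adjusted p = 0.649 with an estimated correlation). By fry its adjusted p was 0.18, so the call held only by camera with the preset correlation. The estimated correlation was 0.09. The loss of the call need not come from correlation, since with 1 residual degree of freedom both other tests have little power. Over all genes tested 0 members passed by limma, and adjusted over the list alone 8 rose and 1 fell. Among those that rose were Gata3, the transcription factor that directs Th2 differentiation (22.7 and 22.1 FPKM in WT, 33.7 and 31.1 in MSC KO-labelled; 0.51 ± 0.09), and the type 2 cytokine genes Il4, Il5 (0.674 and 0.359 FPKM to 5.01 and 2.67 FPKM), Il13 and Il9 (73.8 and 72.1 FPKM to 382 and 291 FPKM). The others were Il3, the chemokine receptor gene Ccr4 and the transcription factor gene Irf4 (63.1 and 65.9 FPKM to 166 and 160 FPKM), and the gene that fell was Ccl1. Beside such counts over a list, 2162 of all 10603 tested genes had an unadjusted p under 0.05. That is a looser rule than the adjustment over a list, so the 2 shares are not on 1 threshold. Part of the shift was in 1 library. Il24, a cytokine gene, was at 176 FPKM in MSC KO 1 and 28.4 FPKM in MSC KO 2 against 16.2 and 22.4 FPKM in WT. Penk, the enkephalin precursor, was at 281 and 29 FPKM against 28.5 and 25.3 FPKM, and Il4ra, the interleukin-4 receptor chain, at 79.1 and 32.1 FPKM against 29.3 and 31.3 FPKM. These 3 genes, and Csf2, the cytokine GM-CSF, which was higher in MSC KO 2 alone (2.54 and 37 FPKM against 1.97 and 2.2 FPKM), were chosen after their values were seen.

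The interleukin-17 helper (Th17) list had a median shift of 1.97 on the log2 scale (1.99 and 1.4 in the 2 tables). The filter takes the mean over all 4 libraries. Members near 0 in WT, such as Il17a and Il22, thus entered through the MSC KO-labelled libraries, while members low in all libraries dropped out. With no filter on low values the median was 1.22 over 18 members. Of 15 tested members 13 were higher in both tables and 0 lower in both. The list rose by camera with the preset correlation (adjusted p = 7.02e-08; adjusted p = 0.649 with an estimated correlation). Over all genes tested 0 members passed by limma, and 11 rose and 0 fell when adjusted over the list alone. These 11 included the cytokine genes Il17a (0.226 and 0.25 FPKM to 3.71 and 10.4 FPKM) and Il17f, and Batf, an AP-1 factor needed for Th17 cells (25.2 and 27.5 FPKM to 188 and 81 FPKM). Il22 was listed at 0 in both WT libraries and at 5.34 and 1.64 FPKM in the MSC KO-labelled ones. Il17a and Il17f lie within 10 Mb of Msc on chromosome 1. Without them the median of the other 13 members was 1.45 and 11 were higher in both tables (camera adjusted p = 1.46e-06; adjusted p = 0.719 with an estimated correlation), a test chosen after the data were seen.

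The Treg list moved in both directions. Of its 29 tested members 12 were higher and 11 lower in both tables. Its median of 0.19 did not pass (camera adjusted p = 0.468) and was -0.02 in the first table alone. Adjusted over the list alone 7 fell and 7 rose, and over all genes tested 0 passed by limma. Those that fell included Foxp3 (X chromosome, mm9, 7135687 to 7182546), Lrrc32, which encodes the TGF-beta docking receptor GARP (23.9 and 26 FPKM to 5.78 and 9.46 FPKM), and Itgae, the integrin CD103 (3.58 and 3.99 FPKM to 1.35 and 0.393 FPKM). Those that rose included Ctla4, an inhibitory receptor (112 and 120 FPKM to 217 and 188 FPKM; 0.8 ± 0.12), and Il10 (0.478 and 0.468 FPKM to 39.6 and 10.1 FPKM). The inhibitory receptor gene Tigit (8.06 and 7.77 FPKM to 28.6 and 22.7 FPKM) rose, as did the homing receptor gene Gpr15 (7.33 and 8.15 FPKM to 31.5 and 33 FPKM). Ikzf2, which encodes Helios, did not pass (9.38 and 9.91 FPKM in WT, 2.06 and 6.66 in MSC KO-labelled; -1.14 ± 0.36). Neither did Il2ra, the interleukin-2 receptor chain CD25 (302 and 317 FPKM, 364 and 307; 0.11 ± 0.12), whose difference was -0.05 in the second table.

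The type 1 helper (Th1) list, too, was mixed (19 tested, median 0.13, camera adjusted p = 0.292). Adjusted over the list alone 6 members rose and 6 fell, and 0 passed over all genes by limma. The interleukin-12 receptor genes Il12rb2 (12.7 and 15.9 FPKM to 59.9 and 50.1 FPKM) and Il12rb1 rose on that adjustment. Both interleukin-18 receptor genes, Il18r1 and Il18rap (4.18 and 4.59 FPKM to 0.642 and 0.563 FPKM), and Eomes, a T-box transcription factor gene (4.81 and 5.16 FPKM to 0.322 and 0.585 FPKM), fell. Ifng, the signature Th1 cytokine, fell on that adjustment (50 and 51.6 FPKM to 33.7 and 42.1 FPKM; -0.42 ± 0.12). Tbx21, which encodes T-bet, did not pass (18.3 and 18.5 FPKM, 22.1 and 28.3; 0.43 ± 0.13). The follicular helper list did not pass (12 tested, median 0.57, camera adjusted p = 0.0568). It passed with no filter on low values (0.0494), with each library rescaled to the same sum (0.0282), without WT 1 (0.0416) and without MSC KO 1 (0.0218), and with small RNA symbols left out (0.0421), a setting chosen after the data were seen. Its member Bcl6, the follicular helper transcription factor, stayed under the filter at 0.857 and 0.641 FPKM in WT and 0.798 and 0.331 FPKM in the MSC KO-labelled libraries. Adjusted over that list alone, Cxcr5, Cd200 and Btla rose and Tox fell. Il21, a cytokine gene, was at 21 and 1.32 FPKM against 0.186 and 0.138 FPKM.

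**Figure D3:**
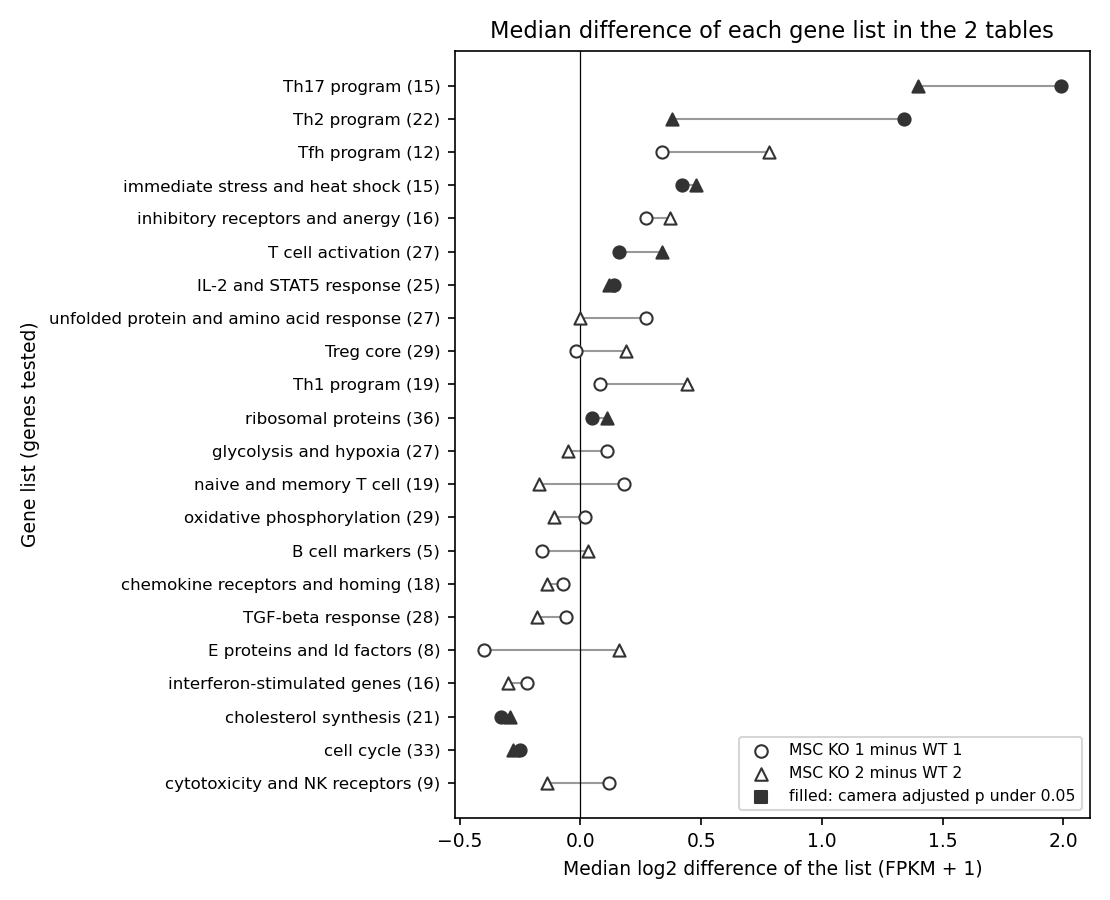
Median log2(FPKM + 1) difference of the tested members of each list (number of genes in brackets) for MSC KO 1 minus WT 1 (circles) and MSC KO 2 minus WT 2 (triangles), filled where camera with the preset correlation gave an adjusted p under 0.05. The Th17 list (1.99 and 1.4) and the Th2 list (1.34 and 0.38) lie above 0, and the cholesterol synthesis list (-0.33 and -0.29) and the cell cycle list (-0.25 and -0.28) lie below 0 in both tables.

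The T cell activation list rose by camera (27 tested, median 0.28, and 0.16 and 0.34 in the 2 tables, adjusted p = 0.000132; adjusted p = 0.649 with an estimated correlation), with 16 members higher and 3 lower in both tables, and 7 up and 1 down when adjusted over the list alone. Il2, the T cell growth factor gene (4.24 and 4.29 FPKM to 33.9 and 26.7 FPKM; 2.56 ± 0.13), Dusp5, a phosphatase of ERK kinases (47.9 and 47.6 FPKM to 103 and 103 FPKM), Irf4 and the early response gene Egr2 were among those that rose, and Xcl1 fell. The interleukin-2 and STAT5 list rose too (25 tested, median 0.21, and 0.14 and 0.12 in the 2 tables, adjusted p = 0.0328; adjusted p = 0.687 with an estimated correlation), as did 5 of its members adjusted over the list alone, with 1 that fell. Socs3, a signalling inhibitor gene (9.83 and 9.62 FPKM to 80.1 and 38.8 FPKM), rose and its relative Socs2 (81 and 86.5 FPKM to 29 and 40.9 FPKM) fell. Without MSC KO 2 the camera adjusted p was 0.0683 for each of these 2 lists, with medians of 0.15 and 0.13, and with no filter on low values it was 0.07 for the interleukin-2 and STAT5 list. The cell cycle list fell (33 tested, 31 lower in both tables, median -0.3, adjusted p = 2.81e-07; adjusted p = 0.649 with an estimated correlation). Its member Top2a, a topoisomerase of dividing cells, was at 100 and 117 FPKM against 143 and 152 FPKM. The cholesterol synthesis list fell (21 tested, 21 lower in both tables, median -0.29, adjusted p = 1.92e-06; adjusted p = 0.649 with an estimated correlation). Mvk, mevalonate kinase, was at 23.7 and 24.3 FPKM against 34.3 and 35.9 FPKM. In neither of these 2 lists did a member pass by limma, over all genes or adjusted over the list alone.

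A list of immediate stress and heat shock genes, which also follows cell handling, rose with the MSC KO label (15 tested, median 0.37, adjusted p = 1.67e-05; adjusted p = 0.649 with an estimated correlation). Atf3, a stress-induced transcription factor gene (6.83 and 6.79 FPKM to 31.5 and 20.6 FPKM), Gadd45b (32.2 and 28.7 FPKM to 73.2 and 95 FPKM) and the chaperone genes Hsph1, Hspd1 and Bag3 rose, as did Egr1, adjusted over the list alone. The ribosomal protein list rose by a median of 0.08 (36 tested, adjusted p = 0.00327; adjusted p = 0.858 with an estimated correlation). Its call ended with no filter on low values (adjusted p = 0.199), with each library rescaled to the same sum (0.0627), with quantile normalization (0.265), without WT 2 (0.0718) and without MSC KO 2 (0.0809). Of the 5 lists of other cell types, only the B cell list had the 3 tested members needed for camera, and it did not pass. The B cell list (5 tested, median -0.06, mean 0.07, test direction down, adjusted p = 0.912) had its largest shared difference in H2-Ab1, a class II histocompatibility gene (32.5 and 33.4 FPKM in WT, 83.2 and 51 in MSC KO-labelled). Of the myeloid list 2 members were tested, of which the more abundant was Cst3, cystatin C (115 and 121 FPKM in WT, 114 and 128 in MSC KO-labelled). The other, the macrophage marker gene Cd68, was at 1.35 and 1.39 FPKM in WT and 3.85 and 3.39 FPKM in MSC KO-labelled libraries. The mast cell and basophil list had 1 tested member, Kit (10.2 and 9.81 FPKM, 2.47 and 14.9), and the erythroid list 1, the erythropoietin receptor gene Epor (0.899 and 1.08 FPKM, 2.53 and 2.51). The CD8 and gamma delta T cell list had 2, with Cd8b1 at 9.75 and 9.75 FPKM in WT and 8.56 and 19.1 in the MSC KO-labelled libraries and Cd8a at 1.58 and 1.9 FPKM, 0.571 and 0.658.

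Other lists did not pass with the preset correlation. The inhibitory receptor and anergy list (16 tested, median 0.35, adjusted p = 0.122) had 8 members that rose adjusted over the list alone, led by Lag3, an inhibitory receptor gene (34.8 and 36.1 FPKM to 140 and 119 FPKM). A further 3 fell. The TGF-beta response list (28 tested, median -0.09, adjusted p = 0.292) had 3 that fell on that adjustment, Nrarp, Ski and the TGF-beta receptor gene Tgfbr1 (26 and 26.2 FPKM to 12.9 and 10.3 FPKM), and 1 that rose, Id1. In the naive and memory list (19 tested, median 0.02, mean -0.22, test direction down, adjusted p = 0.567), 5 members fell and 3 rose adjusted over the list alone. Klf2, Lef1, Foxp1 and Txk were among those that fell, and Satb1, a chromatin organizer (11.1 and 11.6 FPKM to 94.7 and 38.1 FPKM), Ccr7 and Dapl1 rose. The cytotoxicity list (9 tested, median -0.35, mean 0.24, test direction up, adjusted p = 0.912) had granzyme B, Gzmb (63.7 and 67.7 FPKM to 372 and 180 FPKM), up and Nkg7 (288 and 303 FPKM to 173 and 83.7 FPKM) down on its own adjustment. The chemokine receptor list (18 tested, median -0.07, adjusted p = 0.884) had 4 up and 4 down. The interferon-stimulated list (16 tested, median -0.21, adjusted p = 0.136) had Isg15 up and Irgm1 and Zbp1 down on the adjustment over the list alone. The E protein and Id factor list (8 tested, median -0.09, mean 0.02, test direction up, adjusted p = 0.864) had Id1 and Bhlhe40 up and Tcf12 down on that adjustment. The unfolded protein and amino acid response list (27 tested, median 0.2, adjusted p = 0.101) had Atf3 and Cth up on its own adjustment. The glycolysis list (27 tested, median 0.05, adjusted p = 0.32) and the oxidative phosphorylation list (29 tested, median -0.04, adjusted p = 0.545) had no member past either adjustment (0 over all genes by limma). In the glycolysis list the glucose transporter gene Slc2a3 was at 106 and 77.3 FPKM against 46.4 and 49.2 FPKM.

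The authors' deposited tables carry their own test of 1 library against 1, which compares those libraries and not the conditions. By that test the authors' deposited tables called 78 symbols in the first table (60 higher and 18 lower in MSC KO 1) and 67 in the second (43 higher and 24 lower in MSC KO 2). The authors' deposited tables shared 28 of these calls in the same direction, 21 higher and 7 lower, and 0 in opposite directions. Among the 11727 symbols tested in both, the authors' deposited tables called 53 and 39 higher and 18 and 23 lower. Independent lists of those sizes would share 0.176 higher and 0.0353 lower calls of the authors' deposited tables. Whether the 2 tables are independent is not known. If WT 1 and WT 2 came from 1 culture or RNA pool, both tables would be set against the same WT cells and would share more calls. The shared calls higher in the MSC KO-labelled libraries of the authors' deposited tables included Il17f, Il22, Il9, Gzmb, Lag3, Il12rb2, Il23r, the interleukin-23 receptor gene, and Socs3. The shared calls that were lower there, again in the authors' deposited tables, included Coro2a, Foxp3, Il18r1, Itga6, Klf2 and Myb. Of the Th2 list genes that rose when adjusted over the list alone, Il9 was a shared call, and Il3 and Irf4 were called in the second table only. Gata3, Il4, Il5, Il13 and Ccr4 were called by the authors' test in neither table (for Il13, q = 0.0625 and 0.0764). Of the 28, 0 passed limma over the 4 libraries with the table as a block, 19 passed with no table block and 12 with small RNA symbols left out. Of the 38 tested genes within 10 Mb of Msc 0 were called by limma, against 1 of 10565 elsewhere (Fisher's exact test, two-sided, p = 1), a count too small to tell a difference. At an unadjusted p under 0.05 there were 6 of the 36 nearby genes other than Il17a and Il17f, against 2154 of 10565 elsewhere (Fisher's exact p = 0.683).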

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

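The search for high values in rows with no gene symbol was chosen after the other results were seen. These rows, which no comparison above uses, hold about as much of the summed FPKM as the named genes. FPKM is per length, so short entries weigh heavily in that sum, and it is not a share of the fragments. Of 1475 pairs of overlapping unnamed intervals in the 2 tables, 20 were listed at 0 in both WT libraries and at 1 FPKM or more in both MSC KO-labelled ones, and 12 the other way round. The authors' deposited tables marked 4 of the 20, and 0 of the 12, as significant in both tables, and these 4 are given because both tables mark them. That they lie above the WT level of 0 follows from how the 20 were chosen. All 4 are short, 69 to 119 bp in the first table, and positions are mm9. The same number of fragments gives a higher FPKM in such an interval than in a longer gene. The interval on chromosome 2 from 28789744 to 28789822 was at 12610 FPKM in MSC KO 1 and 10894 FPKM in MSC KO 2. The interval on the X chromosome from 149344501 to 149344579 was at 2953 and 4332 FPKM. The interval on chromosome 13 from 21473363 to 21473431 was at 2263 FPKM in MSC KO 1, and the interval from 21473319 to 21473458 that overlaps it was at 149 FPKM in MSC KO 2. The interval on chromosome 5 from 26335215 to 26335333 was at 276 and 263 FPKM. What is transcribed at these 4 places was not looked up, since no annotation of mm9 was at hand, and with 2 libraries per group no single library was tested for standing apart.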

How the results depend on the processing

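The settings with failed estimates kept, the WT libraries averaged as 1 sample, a robust prior and small RNA symbols left out were chosen after the results were seen. With 1 residual degree of freedom, the number of genes changed between MSC KO and WT by limma, 1 at the settings reported, stayed at 1 with pseudocounts of 0.1 and 0.5, summed rows and failed estimates kept, and moved with the other settings. It was 153 with no replicate block, 0 with no filter on low values, 3 at a mean of at least 5 FPKM, 8 with libraries rescaled to the same sum, 0 with quantile normalization, 21 with tables centred on their median and 0 with a prior without trend. Unadjusted p under 0.05 were 2672, 2319 and 2088 in the settings with no filter, quantile normalization and no trend. It was 29 at a threshold of 0.1, 15 with a robust prior, 26 with small RNA symbols left out and 0 with the WT libraries averaged (804 unadjusted). Leaving out 1 library, with no block, gave from 0 (without WT 1, 786 unadjusted; 3 without WT 2) to 2672 (without MSC KO 2; 2301 without MSC KO 1), where the lone sample was assumed to vary like the other group. Across genes, WT 1 minus WT 2 and MSC KO 1 minus MSC KO 2 had a correlation of 0.06, from only 2 pairs. The number of genes at least 2-fold apart in both tables in the same direction was 606 at 1.5-fold, which is the wider limit itself, and the agreement of the 2 tables across genes (Pearson r) was 0.58 with small RNA symbols left out. The Msc difference was 2.47 with a pseudocount of 0.1 and 1.07 with 0.5, against 0.65. The median of the Th17 program list was 1.22 with no filter on low values, against 1.97. The median of the Th2 program list was 0.69 with no filter, 0.38 without replicate 1 and 1.34 without replicate 2. The list kept its call under the other settings and without any single library, but not with an estimated correlation (0.97, adjusted p = 0.649) or by fry (0.97, adjusted p = 0.18). With either, 0 lists passed (camera with the preset correlation gave 8), and with 1 residual degree of freedom both have little power. The stress and heat shock list lost its call too (camera adjusted p = 0.649), though its estimated correlation of -0.03 was below the preset 0.01. The lost calls therefore do not show that correlation between genes made them. The Treg core list ranged from -0.02 to 0.19 without a replicate. The authors' calls numbered 0 at q under 0.01, since the smallest deposited q was 0.0118.

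The direction of the test changed for some uncalled lists. The B cell markers list was at -0.03 with no filter, -0.09 rescaled, -0.1 without MSC KO 1, -0.05 without WT 1 and -0.02 without MSC KO 2. Without WT 2 this list was at -0.2 and its test direction did not change. The cytotoxicity and NK receptors list was at -0.33 with tables centred, -0.42 without WT 1 and -0.35 with WT averaged, and the chemokine receptors and homing list at -0.01 at 5 FPKM. Without MSC KO 1 the glycolysis and hypoxia list was at -0.05 and Il2ra at -0.01, and without a replicate Il2ra ranged from -0.05 to 0.27. Without MSC KO 2 the naive and memory T cell list was at 0.13, the oxidative phosphorylation list at 0.01 and the E proteins and Id factors list at -0.34. Under an unchanged test direction the median changed sign in 6 lists. With no filter the cytotoxicity list was at 0.08, the chemokine receptor list at 0.02 and the E proteins list at 0.02 (0.05 without WT 1, 0.07 without MSC KO 1). The naive and memory list was at -0.02 rescaled and -0.14 without MSC KO 1, the glycolysis list at -0.01 with quantile normalization. The Treg core list was at -0.01 without MSC KO 2. Some lists passed only under an alternative. Without MSC KO 1 the oxidative phosphorylation list fell (adjusted p = 0.00506) and the Th1 program list rose (0.0492), which it also did at 5 FPKM (0.0257). Without MSC KO 2 the glycolysis and hypoxia list (0.00569) and the unfolded protein and amino acid response list (0.00318) rose, and with no filter the interferon-stimulated genes list fell (0.0294). The cause was not tested for any of these moves. Of the other single genes and lists, 2087 comparisons kept their direction (that of the test for lists) and side of the threshold, 250 passed only under the alternative and 14 no longer passed. Depth limits Msc, with 1.1 fragments in each WT library, and other genes near 0 FPKM.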

Other observations

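All tests in this part were chosen after the results were seen, as were the genes named in its first 2 paragraphs, of which 0 passed by limma over all genes. Gbp5, a guanylate-binding protein that interferon-gamma induces, was lower in both MSC KO-labelled libraries, at 8.88 and 4.76 FPKM against 29.3 and 28.9 FPKM in WT. Iigp1, an immunity-related GTPase, was at 8.01 and 5.23 FPKM against 23.6 and 24.6 FPKM. Ifitm3, an antiviral membrane protein, was at 12.9 and 8.16 FPKM against 33.9 and 35.1 FPKM (-1.66 ± 0.20, adjusted p = 0.13), and Tnfsf10, the death ligand TRAIL, at 5.70 and 3.06 FPKM against 18.5 and 19.3 FPKM. These genes were picked, and the interferon-stimulated list given above did not pass (camera adjusted p = 0.136). In that list 9 members were lower and 3 higher in both tables. The AP-1 factor gene Fosl2 was higher in both, at 29.1 and 16.9 FPKM against 4.64 and 4.76 FPKM (2.03 ± 0.23, adjusted p = 0.122), as were Batf3 at 52.7 and 34.2 FPKM against 9.64 and 11.2 FPKM, and Crem at 77.2 and 54.5 FPKM against 21.7 and 22.0 FPKM. Myb, a factor of immature and proliferating blood cells, was at 4.77 and 8.31 FPKM against 39.9 and 40.7 FPKM (-2.49 ± 0.20, adjusted p = 0.114), and Sgk1, a salt-responsive kinase, at 10.5 and 10.5 FPKM against 29.4 and 29.4 FPKM (-1.40 ± 0.09, adjusted p = 0.0992).

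The 2 libraries labelled MSC KO also differed from each other. Nrp1, neuropilin, a surface marker of Treg cells, was at 1.07 FPKM in MSC KO 1 and 172 FPKM in MSC KO 2 against 6.46 and 6.80 FPKM in WT. Ccr6, a chemokine receptor of Th17 cells, was at 10.4 and 111 FPKM against 24.4 and 27.7 FPKM, and Cd80, a co-stimulatory ligand, at 11.5 and 64.6 FPKM against 26.6 and 27.8 FPKM. Plac8 went the other way, at 53.2 and 3.75 FPKM against 8.43 and 9.38 FPKM. The metal-binding metallothionein genes were higher mainly in MSC KO 1, Mt1 at 1330 and 247 FPKM against 236 and 209 FPKM, and Mt2 at 962 and 113 FPKM against 98.5 and 99.9 FPKM. A few genes crossed between the tables, such as Prmt2, an arginine methyltransferase, at 225 FPKM in WT 1 and 186 FPKM in MSC KO 2 against 8.23 FPKM in WT 2 and 8.72 FPKM in MSC KO 1. In a principal component analysis the first component held 49.7% of the variance and separated the labels, and the second held 31.8% and set MSC KO 1 (-27.7) apart from MSC KO 2 (32.9).

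The 2 WT libraries lay closer together than the 2 MSC KO-labelled ones, with a robust SD of their log2 difference of 0.051 against 0.201 in genes of at least 100 FPKM. Deeper sequencing of the WT libraries would lose its effect in abundant genes, but the ratio of the spreads rose from 2.25 at 1 to 3 FPKM to 3.94 there. The WT variance over counting noise grew 1.22-fold from genes of 10 to 30 fragments to genes of over 3000, against 18.59-fold for the MSC KO-labelled libraries. It was 1.97 to 3.09 times counting noise, so that WT 1 and WT 2 may be technical repeats of 1 culture or RNA pool, or separate cultures that differ little, which cannot be told apart from 1 pair of libraries with no labels on their origin (with the WT libraries averaged as 1 sample 0 genes passed by limma, and 804 had an unadjusted p under 0.05). A wider spread of cultures that follows the genotype stays open and was not tested.

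Msc was higher in both MSC KO-labelled libraries, the lowest of them at 13.6 times the highest WT value, where the WT value rests on about 1.1 fragments. An exchange of the WT and MSC KO columns in 1 of the 2 tables would have turned the shared differences against each other, whereas 89.7% of the genes 2-fold apart in both tables went the same way. An exchange of the labels in both tables would put Msc higher in the MSC KO-labelled libraries, as seen in the ratio of 13.6. A targeted allele that still gives Msc transcripts would account for their presence there, but not by itself for the excess over WT. Neither was excluded and Msc cannot tell them apart, since the labels do not give the deleted part and the tables give 1 value per gene. Under an exchange the WT cells, cultured with TGF-beta, would be those with Foxp3 at 2.97 and 7.05 FPKM, against 62.8 and 66 FPKM in the others. TGF-beta induces Foxp3, so the higher level is the one to look for in WT, which is where the labels as given place it. Foxp3 was not used to decide, since it is 1 gene and the labels give no expected level of it. A true effect of the genotype on the locus also stays open and was not tested.

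The Th17 list was higher with Il17a and Il17f, which lie near Msc on chromosome 1, where DNA of another strain may flank a targeted gene. An effect of such DNA on Il17a and Il17f alone does not account for the shift of the 13 members elsewhere. The median of these 13 was 1.45 with 11 of them higher in both tables (camera adjusted p = 1.46e-06, and 0.719 with an estimated correlation). That they lay higher already followed from the counts of the whole list, so leaving out 2 members was no independent test. An effect of such DNA on genes elsewhere would shift those 13 too, so that they cannot decide on it, and it was not tested. Whether such DNA acts on Il17a and Il17f is open. Of the 36 other genes within 10 Mb of Msc 16.7% had an unadjusted p under 0.05 against 20.4% elsewhere (odds ratio 0.781, upper limit 1.91, Fisher's exact p = 0.683), which says nothing of these 2 genes. A biological effect of the genotype on the list stays open and was not tested.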
